A study of Caenorhabditis elegans with 2 samples.

How the data were processed

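The measurements were chromatin immunoprecipitation followed by sequencing (ChIP-seq) with an antibody against AMA-1, the largest subunit of RNA polymerase II, in whole late embryos of Caenorhabditis elegans strain N2 of mixed sex. The 2 samples formed 1 group and were called biological replicates 1 and 2, per the labels. The labels give the embryos' age as unknown, and the immunoprecipitation protocol is not given in the sources used here. No input or other control file was analysed here, so no value below has a background measured in control samples beside it.

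Per the text deposited with the lists, the authors derived a relaxed peak list for each replicate from that replicate's alignments and 1 further file, a further relaxed list from the alignments of both replicates, and a final list from these 3, named as thresholded by the irreproducible discovery rate (IDR). The further file was the same for both replicates, and the text does not say whether it was a control. How the IDR chose the final list is not given in the sources used here. Each list was given on builds ce10 and ce11. The aligner, the peak caller, their versions, the IDR threshold, read filters and read counts are not given in the sources used here, so the depth of each library is unknown and no interval below covers read sampling. The height of a peak is the signal value deposited by the authors, a caller score with no stated scale. It was used only to rank and describe peaks within a list or to compare the same loci in both replicates. That comparison used ranks and, for Pearson's r, the values themselves. The authors' lists also hold a −log10 q-value per peak, which reached only 2.83 in the pooled list and was shared at that value by 342 peaks, so it was not used for ranking. The summit is the position deposited by the authors for each peak.

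On ce11 the relaxed lists held 30000 peaks each and the IDR list 476 peaks (504 on ce10). All 476 IDR peaks had the positions of the 476 highest peaks of the pooled list. Peaks had a fixed width with few exceptions, 350 bp in the pooled and IDR lists, 360 bp in replicate 1 and 340 bp in replicate 2. A width other than 350 bp was found for 21 IDR peaks, among them all of the 12 highest, so interval-based values at the highest peaks rest on unequal widths. The ce11 lists were used throughout, with the ce10 lists only for alternatives of the replicate comparison, and no coordinate was converted between builds. Genes came from the Ensembl release 115 annotation of the same assembly, on chromosomes I to V and X, with 19973 protein-coding genes. All coordinates are 1-based on ce11.

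A summit was near a start or an end when it lay within 250 bp of the annotated start or end of a protein-coding gene. A protein-coding gene had a summit when one lay between 500 bp upstream of its start and its end, and a summit could count for several genes. A non-coding gene had a summit when one lay within 250 bp of its body. The null for positions was 10000 circular shifts of the summits along each chromosome, with a random offset per chromosome, which keeps their spacing. Permutation p-values from the shifts were two-sided, the smallest they can give being 2e-04, except for the overlap of replicates, which was one-sided with 1e-04 as the smallest. Gene lists, the X chromosome and autosome centres were tested with two-sided Fisher's exact tests, and summits at starts against ends with a two-sided exact binomial test. P-values were adjusted by the Benjamini-Hochberg method over the 6 location classes, the 38 gene lists, the 10 non-coding classes with at least 20 genes, or the lists tested for height, at a threshold of 0.05. Confidence intervals of shares are exact Clopper-Pearson intervals at 95% and cover counting error only. GC content was taken over 201 bp centred on the summit. Lists with no member with a summit are given with the share that a count of 0 allows, 3 of the members. Neighbouring genes share summits, so Fisher's exact test over genes treats as separate some that are not. Each gene list was therefore also tested against the shifts and against 10000 random lists matched in 10 classes of gene length.

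The 38 gene lists, the tests, the named-gene rule and most alternatives were fixed before the data were examined. The genes named are those at the 20 IDR peaks with the highest signal value, up to 4 members of each list with the highest summit, and the first 2 members by symbol of each list without a summit. Where a gene outside this rule is named, the text says so. Since both replicates belong to 1 group, no comparison between groups was possible, and each list-based test compares positions or genes within these libraries. The result was recomputed with the 476 highest peaks of each replicate alone, which leaves out the other, with the 238 highest IDR peaks, with the 952 highest pooled peaks, and with other windows and assignments of summits to genes. A set of 217 IDR peaks that were among the 1000 highest of both replicates was added after the replicates had been compared.

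The statistics were tested on simulated peaks before use. In 40 sets of 476 shifted summits no list among the 38 was called and 1 location class was called in error. In 20 sets with 3 planted lists of which 10 members held a summit, 60 of 60 planted lists were called, and a planted excess at gene starts was called in 20 of 20 sets. The other summits of these sets were placed at random. Lists with fewer planted members were not simulated, so this does not give the power for the smaller counts reported below. Of 1000 peaks with 300 planted as shared, 304 were found as shared. Calculations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3, with figures drawn in matplotlib 3.10.9.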

Results

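AMA-1 occupancy was mapped by ChIP-seq in whole C. elegans late embryos, a stage at which organ formation is under way. The series holds 2 biological replicates of 1 condition, each with a ranked list of 30000 relaxed peaks, and a joint IDR list of 476 peaks on ce11. Read depth is unknown for both libraries. The IDR peaks were spread over chromosomes I (89 peaks), II (91), III (91), IV (83), V (67) and X (55). With 1 condition, the questions are how far the replicates give the same peaks and at which genes and positions these lie.

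The replicates shared their highest loci. The peak over cel-mir-52, a microRNA gene, was rank 1 in both lists, and that over sls-2.4, which encodes an SL2 spliced leader RNA, was rank 2 in both. Among the 1000 highest peaks of replicate 1, 272 (27.2%, 95% interval 24.5 to 30.1%) overlapped by at least 1 bp a peak among the 1000 highest of replicate 2. Shifted peaks gave 0.735%, with a one-sided permutation p of 1e-04, the smallest the shifts can give. In the reverse direction 26.2% overlapped. Below the highest loci the heights had little common order. Across 443 IDR peaks with a peak in both lists, Spearman's rho of the signal values was 0.135 (bootstrap 95% interval 0.0278 to 0.233) and Pearson's r was 0.776, or 0.379 on log2 values. These 443 are not all distinct loci, since 12 repeat a pair of replicate peaks already counted, and the interval over cel-mir-52 is listed at ranks 1 and 407 with different summits. With each pair counted once (431 pairs, chosen after the data were seen), rho was 0.0985 with a bootstrap interval that included 0 (−0.00810 to 0.197), and Pearson's r was 0.716, or 0.599 without the pair at cel-mir-52. The IDR peaks are the highest of the pooled list, and choosing peaks by their joint height can lower such a correlation in itself. Over all overlapping pairs of the relaxed lists rho was 0.229. These are correlations across peaks, which are not independent replicates. The IDR list followed replicate 1 more closely, with 389 of its 476 peaks among the 476 highest of replicate 1 and 191 among the 476 highest of replicate 2. In replicate 2, 136 IDR peaks lay below rank 5000 or had no peak, against 2 in replicate 1.

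**Figure D1:**
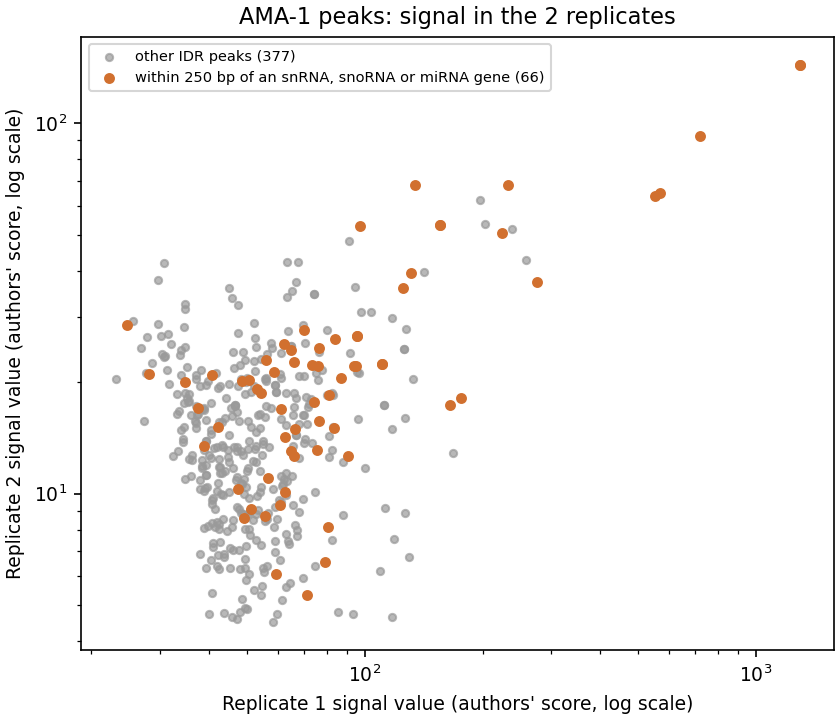
Signal values of the IDR peaks with a peak in both lists, replicate 1 on the horizontal and replicate 2 on the vertical axis, both on log scales in the authors' score units; each point is 1 peak. The peaks within 250 bp of an snRNA, snoRNA or miRNA gene (orange) include the 4 highest, while most other peaks form a cloud with little common order (rho = 0.135 over 443 peaks).

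Short non-coding genes led the list. The highest peak (chromosome IV, 14033763 to 14034454, signal value 1427.6) lay over cel-mir-52, outside protein-coding genes. The next 4 were at SL2 RNA genes, which donate the leader spliced onto downstream messages of operons: sls-2.4 (chromosome I, 4172054 to 4172512, 808.3), sls-2.1 (chromosome II, 5844777 to 5845145, 635.9), sls-2.2 (chromosome II, 5543462 to 5543827, 607.8) and sls-2.8 (chromosome III, 12250396 to 12250669, 312.0). The last of these also fell in the upstream windows of tim-1 and Y75B8A.23. Of the 20 highest peaks, 12 had a summit within 250 bp of an snRNA, snoRNA or miRNA gene. They included a pair of peaks in an intron of F58G1.7 by the snRNA gene sup-6 (ranks 7 and 17), cel-mir-58a in an intron of Y67D8A.2 (rank 11), the snRNA gene sup-39 in an intron of C15F1.5 (rank 13), and the cel-mir-35 cluster in an intron of Y62F5A.9 (rank 19), whose microRNAs are abundant in embryos. At rank 14 the summit lay at the annotated end of hsp-12.3, a small heat shock protein gene, close to the snRNA gene F38E11.11, and at rank 16 the snRNA gene F32B5.9 lay in an intron of cpz-1.

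The other peaks among the 20 highest were mostly at protein-coding genes. The peak at rank 6 lay in the coding sequence of tos-1, 110 bp from its start. Ranks 9 and 10 fell 64 bp and 727 bp inside mdt-26, a Mediator subunit gene, and the first of these also lay upstream of ift-43, an intraflagellar transport gene on the other strand. Introns of ugt-50, a UDP-glucuronosyltransferase gene, held ranks 12 and 20, of which rank 12 was rank 8 in replicate 1 and had no peak in replicate 2. Rank 8 lay over the non-coding gene C30E1.9, and rank 15 lay 98 bp beyond the end of T28F4.1, at rank 14 in replicate 1 and 1366 in replicate 2. Rank 18 was outside genes, upstream of cbp-1 (−901 bp from its start), which encodes a CBP/p300 histone acetyltransferase.

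As classes, snRNA, miRNA and snoRNA genes held far more summits than shifted summits gave. A summit lay within 250 bp of 19 of 129 snRNA genes (14.7%, 52.3-fold), 25 of 261 miRNA genes (9.58%, 34.9-fold) and 27 of 346 snoRNA genes (7.80%, 24.3-fold). Neighbouring genes shared summits, so the 25 miRNA genes stand for fewer loci. The summit at rank 19 counted for cel-mir-35, cel-mir-36, cel-mir-37 and cel-mir-38, and that at rank 152 for cel-mir-42, cel-mir-43 and cel-mir-44, the last 3 named after their values were seen. Among the miRNA genes were cel-mir-54 and cel-mir-55 (peak rank 27), cel-mir-51 (rank 65) and cel-mir-124 (rank 456), named here after their values were seen. Of 18 annotated SL2 RNA genes 10 had a summit, and of 12 SL1 RNA genes 0 had one, which allows up to 3 of 12. This split was made after the values were seen. Whether reads can be placed uniquely at the SL1 RNA genes was not examined, so the absence of summits there does not show an absence of AMA-1. The class of other ncRNA genes was also above the shifts (107 of 7764 genes, 4.93-fold). In part this came from the same summits, such as that over cel-mir-52, so the class is not independent of the others. Each of these 4 classes had an adjusted permutation p of 4e-04, from the smallest p the shifts can give. lincRNA genes were above the shifts in the IDR list (6 of 194, 4.15-fold, adjusted permutation p = 0.0143), but not with replicate 2 alone (1.97-fold, adjusted permutation p = 0.496), the 952 highest pooled peaks (2.46-fold, 0.0650) or the 217 IDR peaks among the 1000 highest of both replicates (2.97-fold, 0.369).

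Pseudogenes (2 of 2128 genes, 0.119-fold, adjusted permutation p = 4e-04) and piRNA genes (12 of 15363, 0.327-fold, adjusted permutation p = 0.0151) held fewer summits than the shifts gave. With replicate 2 alone these folds were 0.288 and 0.134, and for piRNA genes the call ended with the 238 highest IDR peaks (adjusted permutation p = 0.0917) and within 100 bp (0.0982). Genes for tRNA, transcribed by RNA polymerase III, held summits at 4 of 612 genes (2.77-fold, adjusted permutation p = 0.188), which passed no threshold in the IDR list, whereas the highest peaks of replicate 2 alone held summits at 14 (9.69-fold, adjusted permutation p = 4e-04). None of the 20 rRNA genes had a summit, which allows up to 3 of them, and 1 of 100 antisense RNA genes had one (adjusted permutation p = 1.00). Several snRNA genes exist in near-identical copies, so the copy to which their peaks belong is uncertain. Unique placement of reads was not examined at the rRNA genes or at other genes without a summit.

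**Figure D2:**
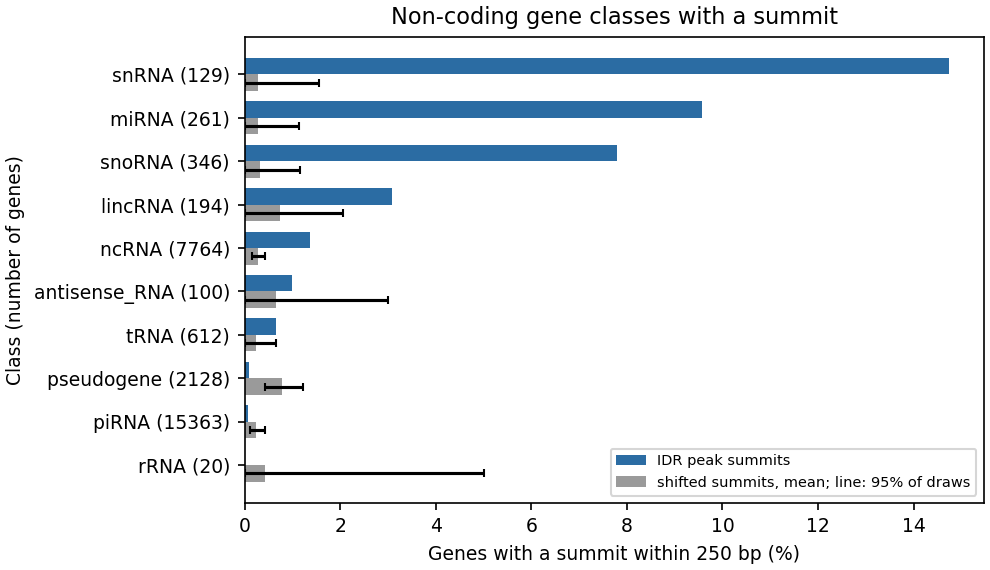
Share of the genes of each non-coding class (number of genes in brackets) with an IDR peak summit within 250 bp (blue), beside the mean over 10000 circular shifts of the summits (grey; black lines span 95% of the shifts). The snRNA (14.7%), miRNA (9.58%) and snoRNA (7.80%) classes stand far beyond the shifted range, while the pseudogene and piRNA classes fall below it.

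Summits gathered at both ends of protein-coding genes. Within 250 bp of a start lay 114 of 476 summits (23.9%), where shifted summits gave 9.72%, and within 250 bp of an end lay 168 (35.3%), where the shifts gave 8.86%. Both shares had an adjusted permutation p of 4e-04, from the smallest the shifts can give. Fewer summits than in the shifts lay inside protein-coding genes (56.1%, 0.877-fold, adjusted permutation p = 0.00312), and in introns (20.2% against 34.1%, adjusted permutation p = 4e-04). Exons held 35.9% against 29.9% (adjusted permutation p = 0.0122), a difference that was lost with replicate 2 alone (32.6%, adjusted permutation p = 0.261), in the 217 peaks of both replicates (30.9%, 0.808) and with the 238 highest IDR peaks (29.8%, 0.989). The lower share inside genes was lost with the 952 highest pooled peaks (61.1%, adjusted permutation p = 0.129). By annotated part, 129 summits lay in coding sequence, 25 in 3' UTRs, 16 in 5' UTRs, 96 in introns and 209 outside protein-coding genes. The share near ends fell to 14.7% with the highest peaks of replicate 2 alone, still above its shifts (adjusted permutation p = 6.00e-04), and was 39.5% with replicate 1 alone.

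**Figure D3:**
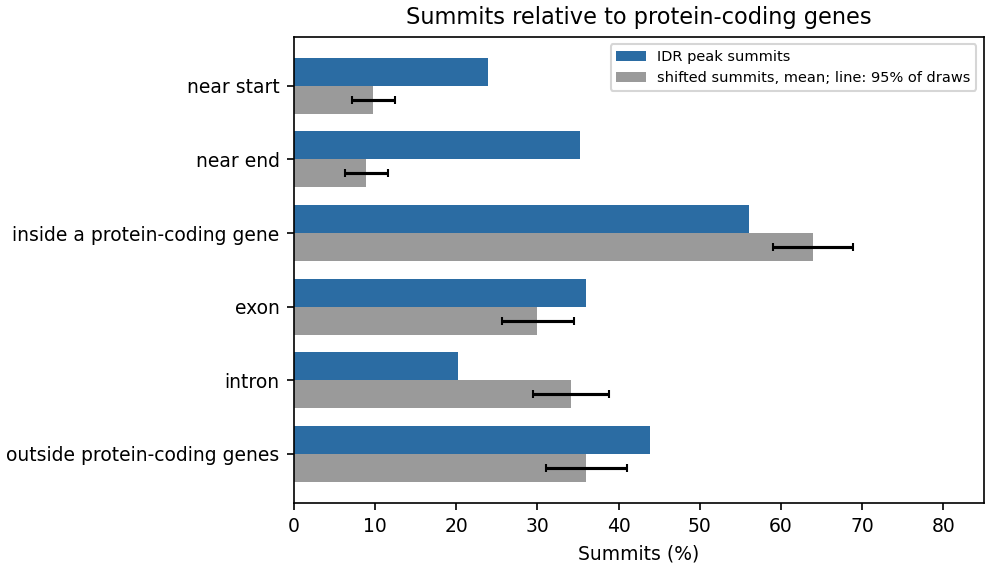
Share of the 476 IDR peak summits in each class of position relative to protein-coding genes (blue), beside the mean over 10000 circular shifts (grey; black lines span 95% of the shifts); near means within 250 bp, and the classes can overlap. The shares near starts (23.9%) and near ends (35.3%) exceed the shifted range, and the share in introns (20.2%) lies below it.

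Among the 476 highest peaks the replicates differed more in summits near ends than near starts. In replicates 1 and 2, respectively, 25% and 26.05% of the summits lay within 250 bp of a start, while 188 (39.5%) and 70 (14.7%) lay within 250 bp of an end. Among the 100 highest peaks the shares near starts were further apart, 25% in replicate 1 and 35% in replicate 2, with 31% and 15% near ends. In the IDR list, 66 summits lay near a start only and 120 near an end only, a start share of 35.5% (95% interval 28.6 to 42.8%, exact binomial p = 9.17e-05). Shifted summits, which keep the spacing, gave 52.7% (unadjusted permutation p = 0.0024). The 476 highest peaks of replicate 1 gave 65 against 134 (32.7%, 26.2 to 39.7%), and those of replicate 2 gave 97 against 43 (69.3%, 60.9 to 76.8%). The lists of the replicates differed by an odds ratio of 4.65 (Fisher's exact p = 2.48e-11), a test of these 2 libraries' peaks and not of a condition. The exact tests treat summits as separate, though some lie close together and some loci are in both lists, so their p-values are too small. In the 217 IDR peaks among the 1000 highest of both replicates, a set added after the data were seen, the start share was 49.4% (exact p = 1.00). Within 100 bp in place of 250 bp it was 52.4% in the IDR list (exact p = 0.744). Summits near ends only were mostly beyond the annotated end, at a median of 139 bp downstream (100 of 120), and those near starts only were centred on the start (median −0.5 bp). In replicate 2, 40 of the 43 summits near ends only lay beyond the end, with a median over the 43 of 144 bp downstream.

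**Figure D4:**
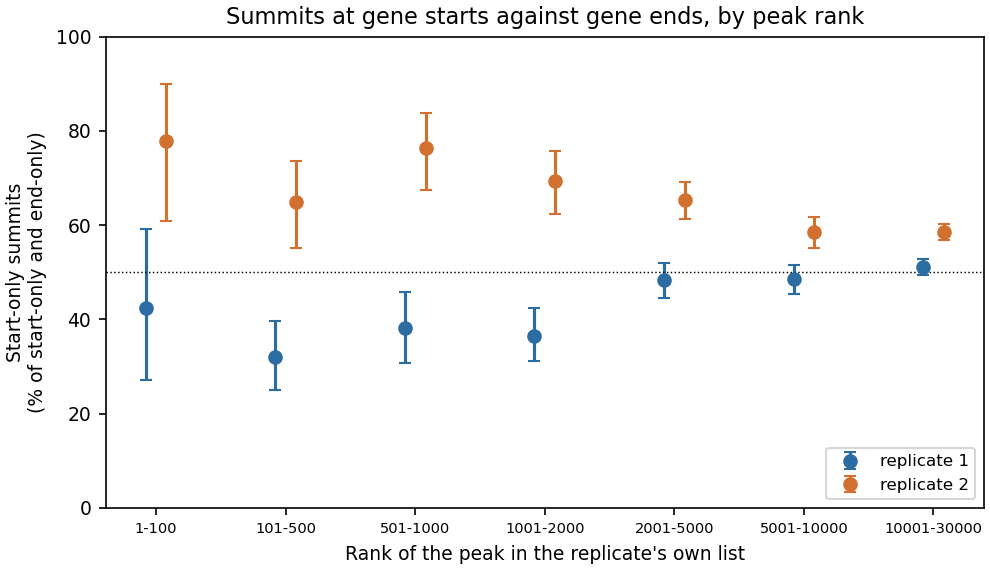
Share of summits near a gene start only among those near a start only or an end only, for bands of peak rank in each replicate's own list (points; bars are exact 95% intervals; dotted line at 50%). Replicate 2 (orange) lies above replicate 1 (blue) in each band, from 77.8% against 42.5% at ranks 1 to 100 to 58.6% against 51.1% in the band of lowest peaks.

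Histone genes stood out among the protein-coding lists. A summit fell in the window of 303 of 19973 protein-coding genes (1.52%). Of 81 histone genes 12 had one (14.8%, 95% interval 7.90 to 24.5%), 10.1 times the share of other genes, with an adjusted Fisher's exact p of 1.26e-07 and 10 different summits. The highest were his-72, which encodes the replacement histone H3.3 (peak rank 29, 35 bp inside the gene), the linker histone gene hil-7 (rank 31), and the neighbouring his-59 and his-60, which shared 1 summit (rank 47). Histone genes share sequence between copies, so for some of these summits the copy is uncertain. The share of 31-base words found once in the genome was 100% at the peaks of his-72 and hil-7, but 70.9% at his-59 and his-60, and 76.6% at his-32, 72.8% at his-31 and 36.9% at his-1 and his-2, the last 4 genes named after their values were seen. How far shared reads raise the histone count was not tested. Ribosomal protein genes had summits at 7 of 82 (8.54%, 5.74 times other genes, adjusted Fisher's exact p = 0.00314), from 6 summits. They included rps-26 (rank 89), rpl-27 (rank 90), rpl-3 (rank 177) and rpl-1 (rank 241). These summits lay away from the gene's own start. They were 427 bp upstream of rps-26 and 30 bp upstream of its neighbour tmem-107, 81 bp before the end of rpl-27, 48 bp before the end of rpl-3, and 463 bp upstream of rpl-1. The summit at rpl-27 also lay in the windows of egl-30 and C53H9.4, and that at rpl-1 in the window of Y71F9AL.9. These neighbours were named after their values were seen. The summit at rps-26 was also within 250 bp of the snoRNA gene F39B2.14, named after its values were seen. Without the 500 bp upstream part of the window the ribosomal list was not called (2.18-fold, adjusted Fisher's exact p = 0.647). Nor was it with the nearest start only (2.59-fold, 0.303), the 238 highest IDR peaks (4.98-fold, 0.223) or the 217 peaks of both replicates (5.05-fold, 0.172).

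Chemoreceptor genes, a large family in which each member is typically expressed in few neurons, held fewer summits than other genes. Only 2 of 1322 had one (0.151%, 0.0937-fold, adjusted Fisher's exact p = 9.57e-06), namely str-208 and srh-171, at ranks 178 and 231, and with replicate 2 alone the ratio was 0.0383. With the 238 highest IDR peaks the list was not called (0.192-fold, adjusted Fisher's exact p = 0.0835). Histones, ribosomal proteins and chemoreceptors were called in all 3 tests, against other genes, shifted summits and length-matched lists. For chemoreceptors the call against the shifts was close to the threshold (0.179-fold, adjusted permutation p = 0.0481). The cilia and intraflagellar transport list passed Fisher's exact test (5 of 73, 4.57-fold, adjusted p = 0.0478), but not the shifts (adjusted permutation p = 0.492), the length-matched lists (0.374) or replicate 1 alone (3.66-fold, adjusted Fisher's exact p = 0.134). Its members were ift-43 (rank 9), tmem-107 (rank 89), the transcription factor gene daf-19 that controls ciliary genes (rank 92), the tubulin acetyltransferase gene mec-17 (rank 413), and arl-13 (rank 416), the last named after its values were seen. The summit at ift-43 was 64 bp inside mdt-26, so it cannot be assigned to the ciliary gene. Of the 2 summits at tmem-107, the higher was shared with rps-26 and the other (signal value 59.76) lay in its coding sequence, 486 bp from its start, in no other protein-coding window. Both lay within 250 bp of the snoRNA gene F39B2.14, so neither can be assigned to tmem-107 alone.

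Of the other 34 lists, which were not called, 22 had at least 1 member with a summit. Among tissue lists these were epidermis and seam (3 of 39, with dlg-1, vab-10 and egl-18), body wall muscle (cpn-3 and act-4 of 40), pan-neuronal genes (unc-44 and unc-108 of 40), neurotransmitter identity (mec-17 of 40) and germline (syp-4 and him-3 of 84). Collagens had 4 of 175, namely dpy-17, sqt-3, col-63 and dpy-14, of which dpy-17 (rank 84, 42 bp upstream of the start) had no peak in replicate 2. Housekeeping lists had 3 of 59 spliceosome genes (snr-4, lsm-6 and snrp-3), 3 of 73 polymerase II machinery genes (mdt-26, taf-4 and mdt-4), 3 of 69 cell cycle and replication genes (cki-1, cye-1 and cdc-25.2), 2 of 63 proteasome and ubiquitin genes (ubq-1 and rpt-1), 2 of 77 oxidative phosphorylation genes (ant-1.1 and cox-4), 2 of 21 V-ATPase genes (vha-12 and vha-1), 2 of 61 cytoskeleton genes (spc-1 and act-4), 1 of 40 translation factors (iff-2) and 1 of 24 glycolysis genes (gpi-1). Stress lists had hsp-12.3 and dnj-13 of 36 heat shock genes, and xbp-1 and crt-1 of 22 ER stress genes. Regulator lists had nhr-49, nhr-236 and nhr-66 of 274 nuclear receptors, and unc-62 and ceh-57 of 97 other homeobox and T-box genes. Among large divergent families there were clec-266 and clec-264 of 346 C-type lectins and innate immunity genes, ugt-50 of 171 cytochrome P450 and UGT genes, and fbxb-72 of 412 F-box, MATH and BTB genes. The summits at hsp-12.3, snr-4, syp-4, mdt-4 and cye-1 also lay within 250 bp of an snRNA, snoRNA or tRNA gene. For snr-4 (rank 33) this was the snRNA gene T11F9.15, and for mdt-4 (rank 362) the snoRNA gene ZK546.18. At cye-1 (rank 252) it was a tRNA gene, and at syp-4 (rank 76) the summit lay inside the snRNA gene H27M09.6. The last 4 of these were examined after the values were seen. Such summits cannot be assigned to the protein-coding gene alone. Adjusted Fisher's exact p-values ranged from 0.149 to 1.00 over the 34.

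The remaining 12 lists had no member with a summit. They were mitochondrial ribosomal proteins (0 of 66, which allows up to 4.55%, 3 of its members), basement membrane (0 of 15, up to 20%), apical matrix and moulting (0 of 24, up to 12.5%), pharynx (0 of 29, up to 10.3%), intestine (0 of 42, up to 7.14%), neuropeptides (0 of 143, up to 2.10%), glia and excretory (0 of 19, up to 15.8%), sperm (0 of 89, up to 3.37%), vitellogenins (0 of 6, up to 50%), early embryo regulators (0 of 36, up to 8.33%), Hox and paralogues (0 of 6, up to 50%), and insulin and lifespan (0 of 68, up to 4.41%). Thus mrpl-1, emb-9, bli-3, abu-1, act-5, flp-1, aqp-8, gsp-3, vit-1, ceh-51, ceh-13 and aak-1 had none. At an overall share of 1.52% these lists are too small for a count of 0 to show a lower share.

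Which lists were called depended on the replicate and on the number of peaks taken. The 476 highest peaks of replicate 2 alone called 7 lists above and 2 below other genes, adding heat shock (6.07-fold, adjusted Fisher's exact p = 0.0293), ER stress (7.43-fold, 0.0403), spliceosome (4.64-fold, 0.0293) and cell cycle and replication genes (3.96-fold, 0.0426) above, and the F-box, MATH and BTB genes below (0 of the family, 0.00650). Those of replicate 1 alone called 4 above and 1 below, adding body wall muscle (6.69-fold, adjusted Fisher's exact p = 0.0232) and epidermis and seam genes (6.86-fold, 0.0232). The differences between the replicates in these lists were not tested. Within the genes with a summit, no list with at least 5 of them stood apart in height. The median height percentile was 68.3 for histones (adjusted permutation p = 0.239), 77.4 for the cilia list (0.239) and 50.2 for ribosomal proteins (0.998).

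Protein-coding genes on the X chromosome had summits less often than autosomal genes. A summit fell in the window of 22 of 2731 X-linked genes (0.806%, 95% interval 0.505 to 1.22%) and 281 of 17242 autosomal genes (1.63%, 1.45 to 1.83%), an odds ratio of 0.490 (Fisher's exact p = 5.30e-04). This test counted genes that can share summits and was not repeated against shifts, which keep the number of summits on each chromosome. X held 55 summits in 17718942 bp and chromosome V 67 in 20924180 bp, while the other autosomes, each shorter than X, held 83 to 91. Chromosomes were not tested one by one. On the autosomes, genes in the middle 50% of a chromosome had one more often than those in the outer arms, with 178 of 9596 (1.85%) against 103 of 7646 (1.35%), an odds ratio of 1.38 (Fisher's exact p = 0.00917). The difference between centres and arms was not called with replicate 2 alone (odds ratio 1.09, Fisher's exact p = 0.472) or with the 238 highest IDR peaks (1.095, p = 0.610), the 217 peaks of both replicates (1.25, p = 0.225) or summits within 500 bp of a start only (1.245, p = 0.217).

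The sequence around summits was richer in G and C than at shifted positions. The median GC content over 201 bp was 42.3% (quartiles 38.8 and 46.3%) against 35.2% for the shifts, with a permutation p of 2e-04, the smallest they can give. The medians for the 476 highest peaks of each replicate were 41.3% in replicate 1 and 45.8% in replicate 2.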

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

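The set of 217 IDR peaks among the 1000 highest of both replicates, the alternatives of the height test, and the rank correlation with each pair of replicate peaks counted once were chosen after the results were seen. Of 216 recomputed values, 175 kept their direction and their side of the threshold or, for counts, stayed within 1.5 times the count reported. Some of these could not change. The shares inside and outside genes, in exons and in introns do not depend on the window around starts and ends. The share outside genes is also the remainder of that inside. Replicate overlap held in 6 of 6 alternatives (21.6 to 46.4%), the rank correlation stayed inside its interval in 3 of 3 (0.0985 to 0.229, the lowest with an interval that included 0), the shares near starts and near ends in 7 of 7 each, the X chromosome difference in 9 of 9 (odds ratio 0.404 to 0.574), GC content in 6 of 6 and the histone list in 12 of 12 (7.04-fold to 33.1-fold). The number of non-coding classes above the shifts stayed at 4 or 5, and no list differed in height in 5 of 5 alternatives.

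The start share was 32.7 to 69.3% when either replicate was left out, reversing without replicate 1, and was 52.4% within 100 bp and 49.4% in the 217 peaks found in both replicates. The odds ratio of centres over arms was 1.09 to 1.32 when either replicate was left out, 1.095 with the 238 highest IDR peaks, 1.25 in the 217 peaks and 1.245 with summits within 500 bp of a start only, and of these it passed the threshold only without replicate 2. The share in exons fell to 29.8% with the 238 highest IDR peaks, on the other side of its shifts. The number of lists above other genes was 4 to 7 when either replicate was left out, 7 with the 952 highest pooled peaks, and 1 with the 238 highest IDR peaks, in the 217 peaks, without the upstream part of the window and with assignment to the nearest start only. The number below was 1 to 2 when either replicate was left out, 3 with the 952 pooled peaks and 0 with the 238 highest IDR peaks. Smaller sets leave fewer genes with a summit, and for the other changes the cause was not tested. The ribosomal list was called in 8 of 12 alternatives, the cilia list in 2 of 12 and chemoreceptors in 11 of 12. Read depth is unknown, so its share in the differences between replicates could not be examined.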

Other observations

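The counts of tRNA genes between replicates, the test of unique sequence at the 20 highest peaks, and the counts of summits per gene were chosen after the results were seen.

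Most genes with a summit had 1. A single summit fell in the window of 261 protein-coding genes, 33 genes had 2, and 9 had 3 or more. T26A8.4, nurf-1 (a chromatin remodelling factor subunit gene), unc-44 (ankyrin) and zfp-1 (a zinc finger chromatin protein gene) had 4 each, and T28F4.1, clec-266, gei-4, gldi-8 and glr-2 had 3 each. In T26A8.4, a gene of 3937 bp, 1 summit lay 75 bp inside the start and the others between 586 and 1548 bp inside. In unc-44, a gene of 29301 bp, the 4 summits all lay in coding sequence. Of the 138 summits in no protein-coding window, 59 lay within 250 bp of a gene end, 25 within 250 bp of an snRNA, snoRNA or miRNA gene, 28 near another non-coding gene only, and 39 near neither an end nor a non-coding gene; the first of these classes can overlap the next 2.

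Among tRNA genes, 14 of 612 had a summit from the 476 highest peaks of replicate 2 and 2 from those of replicate 1. Only replicate 2 had a summit at 13 genes, only replicate 1 at 1 gene, and both at 1 gene. These counts describe the peaks of these 2 libraries, and no test of their difference is given because they prompted the comparison.

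The first pattern weighed is the lower share of starts, among summits near a start only or an end only, in replicate 1 than in replicate 2, whose 476 highest peaks had shares of 25% and 26.05% near starts and 39.5% and 14.7% near ends (100 highest peaks: 25% and 35% near starts, 31% and 15% near ends). The GC content of the lists does not account for all of it, since within 5 classes of GC content the odds ratio was 3.88 (95% interval 2.40 to 6.28), although in the class of highest GC content the start shares were alike (63.6% in replicate 1 and 65.9% in replicate 2). Background confined to the lower peaks of replicate 2 is argued against by its 100 highest peaks, which already had a start share of 77.8% (exact 95% interval 60.8 to 89.9%), above the 32.7% of the 476 highest of replicate 1 and, more narrowly, the 42.5% (27.04 to 59.11%) of its 100 highest. Nor do a few crowded loci carry it, since with 1 summit kept per 5 kb the odds ratio was 7.08 (exact 95% interval 4.08 to 12.5). A difference in depth or in embryo age between the replicates stays open and may account for it. Signal that a control sample would also show stays open too, since it could rank high and the 100 highest peaks cannot tell it apart. Of the tRNA genes, 14 had a summit from the highest peaks of replicate 2 and 2 from those of replicate 1. No biological explanation was tested because the design has 1 group.

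The second pattern is the place of snRNA, snoRNA and miRNA genes among the highest peaks. Reads shared between near-identical copies are argued against as the source of most of the 67 peaks at these genes. Their median share of 31-base words found once in the genome was 100% (bootstrap 95% interval 97.2 to 100%), and 45 of them had 95% or more. The share is taken over the whole peak, so unique sequence beside a repeated gene raises it. Shared reads cannot be excluded for the others, because 14 of the 67 were under 80% and the rest fell between the bounds of 80% and 95%. Many peaks by snRNA genes had lower shares. These were 71.2% and 98.8% at the pair of peaks by sup-6, and 69.4% at the higher peak by sup-39. They were 69.7% at the higher peak by F38E11.11 and 82.5% at that by F32B5.9. The lowest of the 67, 62.5%, was by T11F9.15. Peaks at SL2 RNA genes had a median of 93.9% (77.2 to 100%). For the 12 of the 67 among the 20 highest peaks the median was 88.8%, also between these bounds, so this part cannot be told apart. The shares of these 12 ranged from 69.4% to 100%, with 100% at cel-mir-52. Read length is unknown. Occupancy of neighbouring protein-coding genes is not needed at all of these genes, since 12 of the 213 lying over 500 bp from any protein-coding gene had a summit. Shifts gave 0.582 on average (one-sided permutation p = 1e-04, the smallest they can give). These 12 included sls-2.2 and cel-mir-52. They were 8 miRNA, 2 snoRNA and 2 snRNA genes, so the argument rests mainly on miRNA genes. Among them cel-mir-42, cel-mir-43 and cel-mir-44, named after their values were seen, shared the summit at rank 152. The share was 5.63% for the 213 genes (20.6-fold over the shifts) and 11.3% for the 523 closer to a protein-coding gene (59 genes, 36.7-fold). This difference was not tested. A part played by neighbouring genes at the closer ones stays open, as does signal that a control sample would also show, and no biological explanation was tested.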
